A study of Mus musculus with 8 samples.

How the data were processed

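The lateral ventricle choroid plexus of C57BL/6 mice was profiled by droplet-based single-cell RNA sequencing at 3 postnatal ages. Per the labels, brains were perfused, plexuses of both sexes were pooled for each library and the tissue was dissociated with enzymes before 10x Genomics 3' libraries were made from polyadenylated RNA. The series has 8 samples. Of these, 3 libraries form the P2/3 group (replicates 1 and 2 from day 3, replicate 3 from day 2), 1 library with counts stands for P11, and 3 libraries form the P60 group. The age of the oldest group is called P60 here, as in the sample labels, although the protocol text describes those animals as young adults of a somewhat higher age. For P11 replicate 1 only a list of 18518 barcodes was used to describe the sample, and its counts were not analysed here. Each library is a pool, so p-values measure the spread between pools.

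The deposited files hold raw UMI counts per gene and cell barcode, without normalization, 1 matrix per library, restricted by the authors to barcodes called as cells. The submitters' processing notes name Cell Ranger 5.0.1 and the mm10 build, and the annotation release is not given in the sources used here. Of the 32285 genes in the feature table, 32235 gene IDs were found in GENCODE vM21, from which chromosome, start and end on mm10 were taken.

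The groups, tests, cell filters, clustering settings, gene lists, marker genes, rule for named genes and all alternatives but 2 were chosen before the data were examined. The thresholds for naming clusters, the interaction tests, the free RNA comparisons and the position of P11 between the other ages were set after the data had been seen. Barcodes with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial UMIs were kept. Within each library barcodes were ranked by a simulated-doublet score, and the top 0.8% per 1000 barcodes was removed, which left 34760 cells. Counts were scaled to 10000 per cell and log-transformed. With 3000 variable genes chosen within libraries, 30 principal components and 15 exact nearest neighbours, Leiden clustering at resolution 1 and seed 0 gave 27 clusters, with no integration of libraries. Clusters were named from fixed markers of 17 cell types. A name needed a marker score of at least 0.3, at least 3 markers detected in at least 10% of cells, and at least 1 marker of the type among the 10 leading genes. This naming rule was the second version. The first ranked leading genes against all other cells, most of them epithelial, and did not require a marker of the type among them. It left 4 epithelial clusters with 5972 of the 25987 epithelial cells unnamed and called the Deup1 cluster ependymal. The rule was changed after those names had been seen, so that leading genes were ranked against clusters of other types, and results under the first version are given in the closing section. For the alternative filters and resolutions the naming scale was also changed once, to that of the main clustering, after epithelial clusters had been named erythroid on their own scale. A cluster expressing Deup1 and Ccno, genes of multiciliated cell precursors, met no fixed type and is described on its own. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

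For each class, UMI counts were summed per library over its cells, and libraries with at least 20 cells of the class were fitted in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood, age as the only term). P2/3, P11 and P60 each had a coefficient. The lone P11 library was assumed to vary like the libraries of the other ages. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the class are called changed, and levels (CPM) are counts scaled to a common library total with TMM-adjusted library sizes. Mural cells were not tested in the planned fit, because P60 replicate 1 had 17 of them. The 23 fixed gene lists were tested with camera in limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, adjusted over the lists of the class. Each was repeated, except between P11 and P60, with an estimated correlation and with fry, and members were also adjusted over the list alone. Cell class shares and the share of cells with a UMI of Mki67 or Top2a, counted after each cell was thinned to 2000 UMIs, were compared by two-sided exact permutation tests. With 3 libraries against 3 these cannot give a p under 0.1. Differences between classes in the change from P2/3 to P60 were tested as a class-by-age interaction. Some genes that the rule for named genes picked are not reported here.

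Genes were named by a fixed rule: in epithelial cells the 8 highest and 8 lowest fold changes among called genes with at least 50 CPM in the higher age and no overlap between the libraries of both ages, and in other classes the 5 highest and 5 lowest. In the other classes genes under 0.25 of another class's level were passed over, since free RNA from lysed cells enters every droplet. Predicted, ribosomal, haemoglobin, Xist and Y-linked genes were also passed over. Up to 4 members with the lowest p were named from each list, 3 genes at each end of the P11 steps, and 11 genes always.

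In simulated counts with 200 changed genes, the same fits called 93.9% of epithelial genes changed 4-fold. They called 43.3% of those changed 2-fold and 16.4% of those changed 1.5-fold, with 5 false calls. The changed genes were drawn from those above a minimum count in the smallest library, so genes of low counts were not covered. In the data 7555 epithelial genes were called between P2/3 and P60, far more than 200, so these rates need not hold there. In fibroblasts, endothelial cells and macrophages 98.5%, 98.5% and 100% of the 4-fold changes were called. Between P2/3 and P11, with a single P11 library, 83.3% of the 4-fold and 8.96% of the 2-fold changes were called. Among the simulated lists, which had no effect, camera called 1 of 22 in macrophages and none in the other fits. The simulation was not a test of lists whose genes vary together, so this low number of calls need not hold for them. In the epithelial data between P2/3 and P60 the estimated correlation ran from 0.01004 for interferon response to 0.622 for dissociation genes. The simulation therefore cannot decide whether the list calls at the preset correlation hold.

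The alternatives were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, mitochondrial limits of 15% and 40%, a minimum of 1000 genes, doublet removal left out, Leiden resolutions of 0.5 and 2, a block for the replicate number, the P2/3 and P60 libraries alone, an estimated inter-gene correlation and leaving out each replicate. The 2 alternatives added after seeing the data were the epithelial fits without a cluster of low UMI counts and the epithelial class under the first naming rule. RLE moved the median log2 fold change by about 0.01 at most. Replicate numbers did not pair the libraries: the deviations of same-numbered epithelial libraries correlated at 0.168, -0.211 and 0.242.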

Results

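The data were UMI counts of 32285 genes in single cells of the mouse lateral ventricle choroid plexus, the tissue that secretes cerebrospinal fluid and forms a barrier between blood and brain. P2/3 and P60 had 3 libraries each and P11 had 1, and every library was a pool of animals. Total UMIs per library were 228733923, 33342563 and 91471653 in P2/3 replicates 1 to 3, 161571647 in the P11 library, and 148145348, 182510235 and 202437184 in P60 replicates 1 to 3. The median barcode held 20644, 6124 and 17166 UMIs at P2/3, 22658 at P11, and 6595, 5282 and 13824 at P60. Mitochondrial UMIs took a median of 5.95%, 2.76% and 5.07% of a barcode's counts at P2/3, 4.30% at P11, and 24.9%, 12.2% and 10.1% at P60. The limit of 25% mitochondrial UMIs was exceeded by 12.4%, 0.332% and 4.74% of barcodes at P2/3, by 7.03% at P11 and by 49.9%, 24.0% and 24.7% at P60. Day of preparation and sequencing batch are not given in the labels, so batch and age cannot be told apart.

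The first question was which cell types the plexus held at each age. Secretory epithelial cells, recognised by Folr1, Kl and Kcnj13 among others, were the largest class, and fibroblasts, endothelial cells, macrophages and mural cells, the contractile cells of vessel walls, were also found. Macrophages, T or NK cells and B cells took a larger share of named cells in every P60 library than in any P2/3 library. Macrophages made up 1.80% ± 0.736 (SD, n = 3) at P2/3, 2.34% at P11 and 5.40% ± 1.78 at P60 (two-sided exact permutation p = 0.1, adjusted p = 0.3). For T or NK cells the shares were 0.0780% ± 0.050 at P2/3, 0.176% at P11 and 0.881% ± 0.536 at P60, and for B cells 0.0789% ± 0.0687, 0.137% and 0.421% ± 0.276, with the same exact p of 0.1 and adjusted p of 0.3. For B cells the separation rested on 8 cells in P60 replicate 3 (0.141%) against 5 in P2/3 replicate 3 (0.125%), and it was lost with the 15% mitochondrial limit and under the first naming rule (exact p = 0.2 each). Without P60 replicate 1 the B cell difference was 0.205 points. The smallest p that 3 libraries against 3 allow is 0.1, so no share could pass 0.05, and under no difference 10% of such comparisons would separate the ages fully. The epithelial share was 75.8% ± 3.86 at P2/3, 74.8% at P11 and 75.7% ± 5.58 at P60 (exact p = 1, adjusted p = 1), and the sign of that difference changed when P2/3 replicate 2 (2.13 percentage points) or P60 replicate 2 (2.65) was left out. Fibroblasts took 7.95% ± 0.429 at P2/3, 9.36% at P11 and 5.84% ± 3.12 at P60, and endothelial cells 5.11% ± 2.26, 6.14% and 10.3% ± 2.58. Mural cells took 1.95% ± 0.357, 2.95% and 1.10% ± 0.856, and erythroid cells 0.903% ± 1.39, 0.273% and 0.0673% ± 0.0454. Neutrophils took 0.195% ± 0.0288, 0.0780% and 0.121% ± 0.160. Among non-epithelial cells alone, endothelial cells took 20.6% ± 6.84 at P2/3 and 42.3% ± 2.67 at P60, and macrophages 7.30% ± 2.16 and 22.5% ± 6.70 (exact p = 0.1 and adjusted p = 0.2 for both). Non-epithelial cells as counted here include the Deup1 and Ccno cluster described next, which made up 15.7%, 29.0% and 32.4% of them in the P2/3 libraries and at most 1.04% at P60, so its loss alone raises the other shares. Its 2 main parts held the epithelial genes Folr1 at 1111 and 1204 CPM and Otx2 at 383 and 334 at P2/3. The epithelial class held 1398 and 267 CPM. The epithelial shares above leave this cluster out. It took 4.15%, 5.72% and 8.55% of named cells in P2/3 replicates 1 to 3 and 0.139%, 0.102% and 0.194% in P60 replicates 1 to 3. An epithelial share with it added was not tested.

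**Figure D1:**
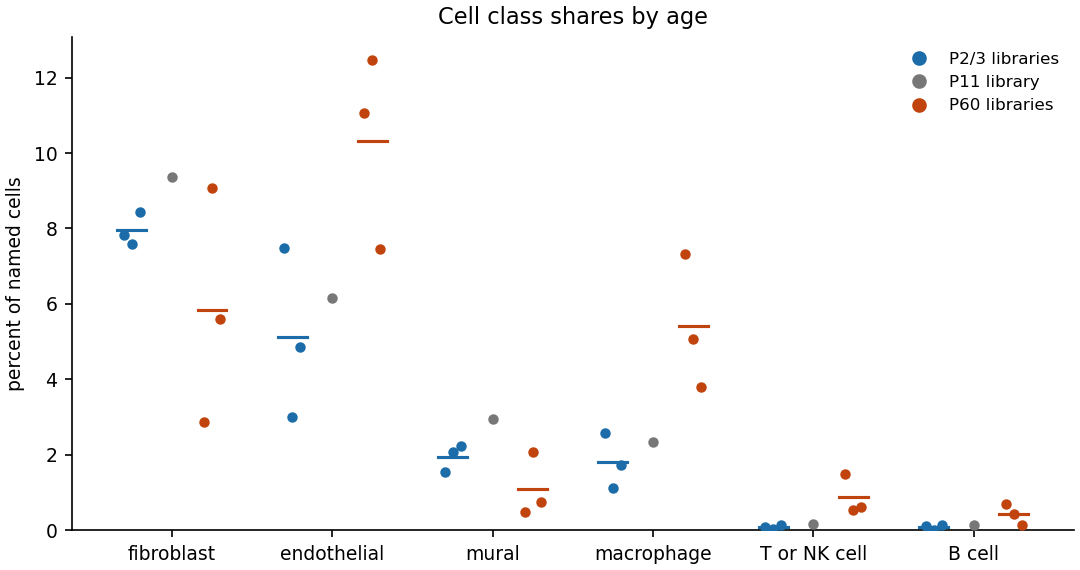
Share of named cells (%) taken by fibroblasts, endothelial cells, mural cells, macrophages, T or NK cells and B cells at P2/3, P11 and P60. Points are libraries, and bars are the means where there were 3. Macrophages lay at 5.40% ± 1.78 at P60 against 1.80% ± 0.736 at P2/3.

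A cluster of 1077 cells with Nkain2, Cdc20b, Deup1 and Ccno among its 10 leading genes held 296, 226 and 343 cells in the P2/3 libraries, 191 at P11 and 5, 5 and 11 at P60. In that cluster 16.2% ± 0.912 of cells had a UMI of Mki67 or Top2a, markers of dividing cells, at P2/3 after thinning to 2000 UMIs, 10.7% at P11 and 0% at P60, with cells under 2000 UMIs left out here and below. These values compare different parts of the cluster: at P2/3 a part of 406 cells with Deup1 at 282 CPM had Top2a at 155 CPM and a part of 453 cells with Deup1 at 26.2 CPM had it at 14.4, and 20 of the 21 cells at P60 lay in the latter. Among epithelial cells the share was 0.115% ± 0.0355 at P2/3, 0.0756% at P11 and 0.00701% ± 0.00928 at P60 (two-sided exact permutation p = 0.1, n = 3 and 3, the smallest possible). Before thinning, 109 of 11366 epithelial cells at P2/3 and 10 of 10785 at P60 had such a UMI. The Deup1 and Ccno cluster, counted apart from them, had it in 358 of 865 cells at P2/3. At a resolution of 2 its part with high Deup1 had the cell cycle genes Cdk1 and Cenpf among its leading genes. The low epithelial share therefore follows in part from how the classes were split. In macrophages the thinned share was 7.52% ± 2.30, 15.3% and 2.91% ± 1.11, where 65 of 297 cells at P2/3 were left out and P2/3 replicate 2 kept 18 of 44, and in fibroblasts 2.74% ± 1.10, 5.01% and 0.220% ± 0.0887.

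The second question was how epithelial cells changed between the first postnatal days and P60. When epithelial cells were clustered alone, clusters led by Rdh5, Tenm2 and Spink8 with 5165, 3318 and 416 cells held 0 cells of the P2/3 libraries, and those led by Klk4, Meg3 and Rmrp with 5141, 2883 and 3172 held at most 0.0290% of the epithelial cells of a P60 library. As in fibroblasts and endothelial cells, the change compares largely different clusters. These clusters were made from the same counts without integration. Their split by age cannot tell whether cell populations or levels within them changed. Among the genes with the highest fold changes were Prlr, the prolactin receptor, Scd1, a fatty acid desaturase, and Cox8b, a subunit of respiratory complex IV. Among those with the lowest were Col9a2, a collagen chain, Gpc3, a proteoglycan that restrains growth, and Igfbpl1, a binding protein of insulin-like growth factors. The lysophospholipase Enpp2 and the anti-ageing hormone Kl also rose. Ttr, the thyroid hormone carrier that took the largest part of epithelial counts, was not called changed.

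Of 19456 genes tested in epithelial cells by edgeR, 7555 were called, 3590 higher and 3965 lower at P60, from class totals of 27113741 to 172701268 UMIs per library. Without P60 replicate 1 the count was 4821. Cox8b (ENSMUSG00000025488, mm10 chr7:140898945-140900446) had a log2 fold change of 10.96 ± 0.61 (SE, adjusted p = 1.35e-05), from 0.143 ± 0.104 CPM (SD, n = 3) through 10.4 at P11 to 323 ± 131. Prlr (ENSMUSG00000005268, chr15:10177238-10349180) had 9.91 ± 0.37 (adjusted p = 3.69e-06), from 1.47 ± 0.521 CPM through 133 to 1428 ± 44.1. Scd1 (ENSMUSG00000037071, chr19:44394455-44407879) had 6.74 ± 0.36 and reached 58.1 ± 14.5 CPM. Trf, Hemk1, Maob and Itgb8 followed at 4.41, 4.32, 4.17 and 4.06. Col9a2 (ENSMUSG00000028626, chr4:121039385-121055322) had -11.18 ± 0.48 (adjusted p = 5.93e-06), from 77.3 ± 30.4 CPM through 5.80 to 0.0334 ± 0.00884. Gpc3 (ENSMUSG00000055653, chrX:52272426-52613950) had -9.75 ± 0.26 (adjusted p = 2.53e-06), from 179 ± 10.9 CPM through 21.8 to 0.212 ± 0.0612. Igfbpl1 (ENSMUSG00000035551, chr4:45809468-45826923) had -5.11 ± 0.24 and Slc6a15 (ENSMUSG00000019894, chr10:103367783-103419377), an amino acid transporter, -5.04 ± 0.21, from 511 ± 85.2 to 15.6 ± 0.982 CPM. Slit3, Anxa2, Meg3 and Wfikkn2 followed at -3.58, -3.57, -3.37 and -2.98. Leaving out 1 library moved some of these by over 1.5-fold: Meg3 (45.6, 37.7 and 116 CPM at P2/3) was -2.69 without P2/3 replicate 3, and without P2/3 replicate 1 Cox8b was 12.24 and Scd1 7.34.

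Among genes named whatever their result, Enpp2 (ENSMUSG00000022425, chr15:54838901-54952892) rose by 3.62 ± 0.30 log2 (adjusted p = 7.08e-05), from 1425 ± 500 to 17480 ± 1871 CPM. Kl (ENSMUSG00000058488, chr5:150952607-150993817) rose by 3.08 ± 0.32 (adjusted p = 2.36e-04), from 125 ± 42.1 to 1053 ± 312 CPM. Igf2 (ENSMUSG00000048583, chr7:142650766-142666816), a fetal growth factor, rose by 1.12 ± 0.19 (adjusted p = 0.00274), from 250 ± 35.2 to 545 ± 83.4 CPM. Ttr (ENSMUSG00000061808, chr18:20665280-20674321) had a log2 fold change of -0.26 (adjusted p = 0.415) with 274900 ± 68520 CPM at P2/3, 455200 at P11 and 229400 ± 22460 at P60. The folate receptor Folr1 (-0.17, adjusted p = 0.564), the cilia regulator Foxj1 (0.00, adjusted p = 0.991) and the class I chain H2-K1 (0.63, adjusted p = 0.103) were not called. B2m, its light chain, was called at 0.90 ± 0.27 (adjusted p = 0.0312), but not without P2/3 replicate 2 (adjusted p = 0.0627), P2/3 replicate 3 (0.105) or P60 replicate 1 (0.116), nor under the first naming rule (0.0898). Mki67 fell by 4.47 (adjusted p = 0.00311) on 39 UMIs at P2/3 and 2 at P60.

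**Figure D2:**
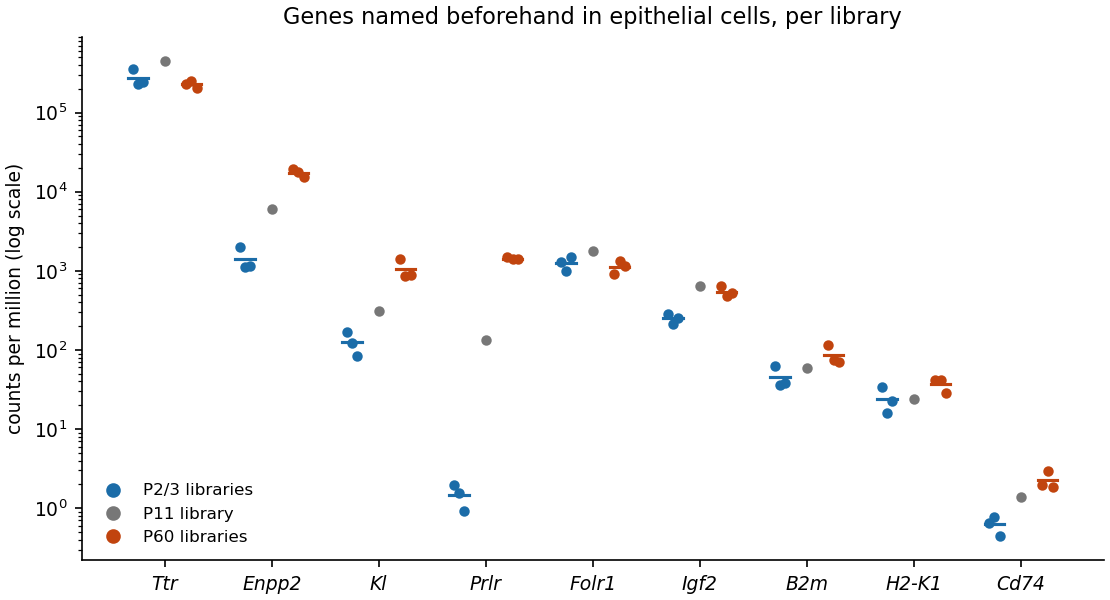
Level in CPM on a log axis of genes named in epithelial cells, with a point for each library at P2/3, P11 and P60. Prlr lay at 1.47 ± 0.521 CPM at P2/3, 133 at P11 and 1428 ± 44.1 at P60.

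Gene lists fixed beforehand showed higher ion transport and energy metabolism at P60 at the preset correlation. With an estimated correlation camera called none of them, at an adjusted p of 0.497 for ion transport and 0.421 for cholesterol synthesis, glycolysis, oxidative phosphorylation and mitochondrially encoded genes. Of 21 cholesterol synthesis genes 16 rose and 0 fell (19 and 0 when adjusted over the list alone), including Sc5d (1.81), Nsdhl (1.62) and Ebp (1.56), with a camera adjusted p of 2.15e-07. Glycolysis had 12 of 18 higher and 1 lower (12 and 1 over the list alone, adjusted p = 3.23e-04), including Hk1 (1.24) and Ldhb (1.78). Nuclear genes of oxidative phosphorylation had 16 of 39 higher and 0 lower (19 and 0 over the list alone, adjusted p = 3.39e-04), including Uqcrc2 (0.91) and Cycs (0.94). Mitochondrially encoded genes had 10 of 13 higher and 0 lower, also over the list alone (adjusted p = 0.00106), including mt-Nd2 (1.73), and the P60 barcodes held more mitochondrial UMIs. Ion and water transport had 12 of 20 higher and 1 lower (14 and 2 over the list alone, adjusted p = 0.00121), including the potassium channel Kcnj13 (1.63) and Atp1b1 (1.41). Solute and vitamin transport had 8 of 20 higher and 2 lower (9 and 2 over the list alone) and was not called (adjusted p = 0.0821), including the thyroid hormone carrier Slco1c1 (2.47). Secreted proteins and receptors had 8 of 23 higher and 5 lower (9 and 5 over the list alone, adjusted p = 0.229), with Wnt5a at -4.04.

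Growth and matrix lists were lower at the preset correlation. With an estimated correlation camera called none of the 4 in this paragraph, each at an adjusted p of 0.421. Of 29 collagen and matrix genes 20 fell and 2 rose (21 and 2 over the list alone), including the basement membrane chains Col4a1 (-3.87) and Col4a2 (-4.25), with an adjusted p of 2.00e-06. Epithelial libraries held fibroblast marker RNA at 0.772% ± 0.139 of the fibroblast level at P2/3, 0.279% at P11 and 0.0498% ± 0.0178 at P60. Imprinted growth genes had 10 of 18 lower and 2 higher (11 and 2 over the list alone, adjusted p = 0.0101), including Grb10 (-2.12) and Nnat (-4.22, and -3.44 without P2/3 replicate 2). Proliferation genes had 10 of 26 lower and 0 higher, also over the list alone (adjusted p = 0.0182, and 0.0728 without P2/3 replicate 1), including Hmgb2 (-2.08). Angiogenesis genes had 9 of 23 lower and 1 higher, also over the list alone (adjusted p = 0.0208, and 0.0728 without P2/3 replicate 1), including Kdr (-1.55) and Mcam (-2.82). Kdr is also a fixed marker of endothelial cells. Endothelial RNA in epithelial cells was not measured and stays open for this list.

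Immune genes were asked about because the series concerns early immune gene activation. Of 35 interferon response genes 14 rose and 1 fell (15 and 1 over the list alone), including Ifi27 (3.69, from 68.8 to 886 CPM), Ifi27l2a (6.33) and Irgm1 (4.01), with an adjusted p of 0.00138. With an estimated correlation that became 0.421, as for innate sensing and MHC class II, with 0.493 for MHC class I. For interferon response the estimate of 0.01004 was close to the preset 0.01, yet the unadjusted camera p went from 4.20e-04 to 0.0243. A higher correlation does not account for that loss, so the 2 forms of camera differ in more than the correlation. Innate sensing had 9 of 19 higher and 1 lower (10 and 2 over the list alone, adjusted p = 0.0182, and 0.0506 without P2/3 replicate 3), including the receptors Tlr4 (3.1) and Tlr3 (1.89). MHC class I had 7 of 19 higher and 1 lower, also over the list alone (adjusted p = 0.0265), including H2-T23 (1.94), Tap2 (1.77) and Psmb8 (-2.54), and the list was not called without P2/3 replicate 2 (0.0653) or under the first naming rule (0.0782). MHC class II had 5 of 7 higher and 1 lower (5 and 2 over the list alone, adjusted p = 0.0602). Cd74 rose by 1.89 ± 0.31 (adjusted p = 0.00208) from 0.625 to 2.27 CPM, H2-Aa by 5.54 (6.35 without P2/3 replicate 1) from 0.0117 to 0.821 CPM and H2-DMb1 by 1.41 from 5.89 to 15.8 CPM. At P60 the epithelial level of H2-DMb1 was 8.03% of the macrophage level, that of Cd74 0.0270%, and that of macrophage markers 0.0265% ± 0.00627.

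Camera called none of the remaining lists. Tight and adherens junctions had 4 of 20 higher and 7 lower (5 and 8 over the list alone, adjusted p = 0.777), including Marveld3 (1.81). Motile cilia had 6 of 27 higher and 7 lower (7 and 7, adjusted p = 0.672), including Rsph1 (1.35) and Ccdc40 (-3.49). Complement had 4 of 17 higher and 3 lower (4 and 3, adjusted p = 0.624), including Cd59a (2.58). Cytokines and NF-kB had 6 of 29 higher and 2 lower (2 and 2, adjusted p = 0.275), including Il1r1 (1.58). Dissociation and immediate early genes had 5 of 25 higher and 3 lower (3 and 3, adjusted p = 0.672), including Nr4a1 (-1.94). Fenestrated and barrier endothelium genes had 6 of 17 higher and 3 lower (6 and 3, adjusted p = 0.408), where the median of -0.08 and the mean of 0.26 differed in sign. Border macrophage genes had 2 of 11 higher and 3 lower (2 and 3, adjusted p = 0.672), and microglia-like genes 3 of 13 higher and 6 lower (3 and 6, adjusted p = 0.672). All 12 epithelial lists called at the preset correlation were also called by fry, which called 15, among them MHC class II (0.00667), secreted proteins (0.0293) and fenestrated and barrier endothelium (0.0122), and none of the 12 was called by camera with an estimated correlation (2 at an unadjusted p under 0.05).

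**Figure D3:**
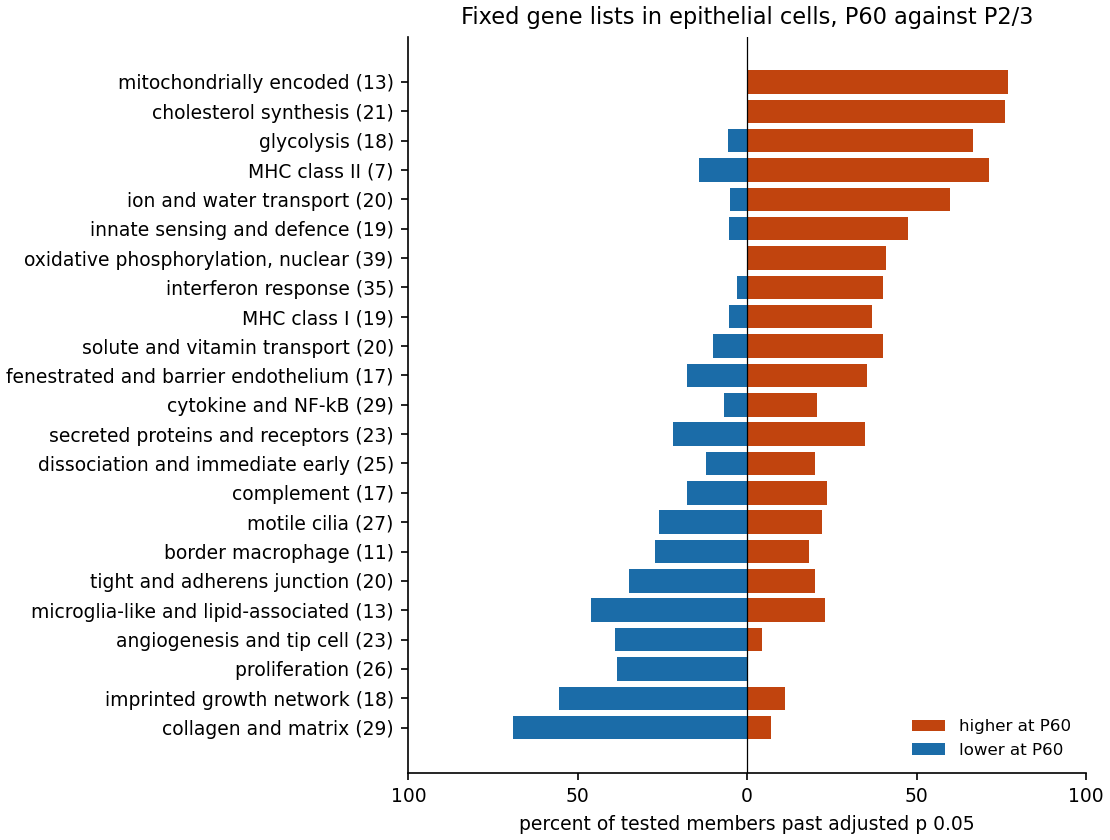
Percent of the tested genes of each list called higher and lower at P60 than at P2/3 in epithelial cells, with the number tested in brackets. Cholesterol synthesis had 16 higher and 0 lower of 21, and collagen and matrix 2 higher and 20 lower of 29.

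The third question was which epithelial changes had begun by P11. Prlr was already higher at P11 than at P2/3, by 6.49 ± 0.35 log2 (adjusted p = 9.01e-04), as was Igfbp7 (3.54, from 13.1 to 153 CPM). Gpc3 (-3.03, adjusted p = 0.00803), Slc6a15 (-2.54, adjusted p = 0.00981) and Col9a2 (-3.74, adjusted p = 0.0168) were lower, the last not without P2/3 replicate 3 (adjusted p = 0.0663) or P60 replicate 1 (0.0588). From P11 to P60 Cox8b (4.96, adjusted p = 0.00691), Scd1 (4.89, adjusted p = 0.00169) and Prlr (3.43, adjusted p = 0.00408) rose, and Igfbpl1 (-4.28, adjusted p = 1.69e-04), Slit3 (-2.66) and the cell cycle inhibitor Cdkn1a (-2.63) fell.

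Between P2/3 and P11 edgeR called 283 genes, 154 higher and 129 lower, of 2964 with an unadjusted p under 0.05. This count was unstable: it was 606 without P2/3 replicate 2, 33 without P2/3 replicate 3, and 65, 94 and 108 without P60 replicates 1, 2 and 3. It was 144 under the first naming rule and 1017 by DESeq2, and with a block for the replicate number edgeR called 0, with 2552 unadjusted. Lists called were oxidative phosphorylation (1.64e-11), glycolysis and cholesterol synthesis (8.46e-06 each), ion transport and secreted proteins (6.33e-04 each), dissociation genes (0.00305), innate sensing (0.0163) and MHC class I (0.0437), all higher, and motile cilia (0.0217), lower. Neither fry nor camera with an estimated correlation called any of them, where 0 lists also had an unadjusted p under 0.05 (adjusted p = 0.717 for dissociation genes and 0.680 for the others). Single genes past the threshold were few in these lists: 1 of 39 in oxidative phosphorylation, 3 of 23 in secreted proteins and 2 of 19 in innate sensing were higher, 1 of 27 in motile cilia was lower, and none passed of 18 in glycolysis, 21 in cholesterol synthesis, 20 in ion transport, 25 dissociation genes and 19 in MHC class I. The call of dissociation genes was lost without P2/3 replicate 1 (0.0730) and that of innate sensing without P2/3 replicate 3 (0.0554). Between P11 and P60, 1288 genes were called, 478 higher and 810 lower. The count was 2639 without P2/3 replicate 2, 832 without P2/3 replicate 3, and 467, 776 and 571 without P60 replicates 1, 2 and 3. Lists called lower were collagen and matrix (5.90e-10, 10 of 29 genes lower and 1 higher), proliferation (9.18e-04, 4 of 26 lower), imprinted genes (0.00972, 2 of 18 lower) and dissociation genes (0.00972, and 0.0834 without P60 replicate 3, 1 of 25 lower). Lists called higher were interferon response (1.22e-06, 6 of 35 genes higher and 0 lower), cholesterol synthesis (2.00e-04, 2 of 21 higher) and mitochondrially encoded genes (0.00469), of which none of 13 passed alone. With a single P11 library, camera's estimated correlation and fry gave values for this step that changed with numerical rounding, and they are left out. They were left out after their outcome had been seen. In the last run that held them the estimated correlation called no list and fry only interferon response, proliferation and collagen and matrix.

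In fibroblasts, the cells of the plexus stroma, Erc2, best known from synapses, and Coch, a matrix protein of the inner ear, rose, while Fn1, fibronectin, and Spock3, a proteoglycan, fell. The ages lay largely in different clusters: 1 fibroblast cluster, led by Coch and Alpl, held 97, 386 and 280 cells in the P60 libraries and 0 at P2/3, and another held 473, 286 and 306 cells at P2/3 and 0, 0 and 1 at P60. The change within the class therefore compares different clusters. Of 13233 genes 1969 were called, 1013 higher and 956 lower, with 1202, 1127, 1244 and 1061 called without P2/3 replicate 3 and P60 replicates 1, 2 and 3. Erc2 (ENSMUSG00000040640, chr14:27622428-28478537) had 6.38 ± 0.34 (adjusted p = 1.50e-05), from 6.19 ± 2.96 CPM through 44.0 to 430 ± 91.2. Coch (ENSMUSG00000020953, chr12:51593341-51605771) had 5.86 ± 0.35, from 38.0 ± 12.1 CPM through 133 to 2114 ± 478. Adamtsl2 followed at 5.92, Adra2c at 5.42 and Inmt at 4.79. Fn1 (ENSMUSG00000026193, chr1:71585520-71653200) had -5.76 ± 0.40 (adjusted p = 2.41e-05), from 164 ± 23.1 CPM through 59.0 to 3.78 ± 2.84, and Spock3 (ENSMUSG00000054162, chr8:62951009-63357103) -4.81 ± 0.43. Tenm2, Sema3a and Npnt followed at -4.25, -3.81 and -3.74. Without P60 replicate 2 Fn1 was -5.12 and Spock3 -5.70, and without P2/3 replicate 1 Adamtsl2 was 6.89 and Adra2c 6.25.

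Camera called 12 fibroblast lists at the preset correlation. With an estimated correlation camera called 0 of them, with 4 at an unadjusted p under 0.05 and an adjusted p of 0.128 for proliferation and imprinted genes and 0.273 for interferon response and cytokines. Of the 12, fry called 6, and not collagen and matrix (0.0555), oxidative phosphorylation (0.0958) or ion transport (0.197), among others. Fibroblast proliferation genes had 22 of 28 lower and 0 higher (23 and 0 over the list alone, camera adjusted p = 1.31e-14), including Top2a (-5.59, and -5.00 without P60 replicate 2). Imprinted genes had 13 of 18 lower and 0 higher (14 and 0, adjusted p = 3.33e-08), including Peg3 (-2.09) and Igf2 (-2.37, from 360 to 69.8 CPM). Interferon response had 19 of 37 higher and 1 lower (28 and 1, adjusted p = 1.16e-12), including Gbp2 (2.21), and MHC class I 10 of 17 higher and 0 lower (10 and 0, adjusted p = 3.40e-08), including H2-K1 (3.40, and 3.99 without P2/3 replicate 1) and H2-D1 (3.36). Cytokines had 10 of 26 higher and 0 lower (10 and 0, adjusted p = 5.82e-06), including Cx3cl1 (2.38), and complement 7 of 14 higher and 1 lower (7 and 1, adjusted p = 0.00215), including C1ra (2.42). Collagen and matrix had 13 of 29 lower and 4 higher (14 and 5, adjusted p = 0.00247), including Postn (-2.49) and Col15a1 (3.38, and 4.23 without P2/3 replicate 3). Oxidative phosphorylation was lower (1.29e-04, 6 of 39 genes). Ion transport (0.00234), cholesterol synthesis (0.00322, and 0.140 without P60 replicate 2), mitochondrially encoded genes (0.0103, and 0.129 without P60 replicate 1) and secreted proteins (0.0366, and 0.231 without P2/3 replicate 2) were higher. The ion transport and secreted protein lists were drawn up for epithelial cells, and epithelial markers in fibroblasts lay at 3.68% ± 2.26 of the epithelial level at P2/3 and 6.07% ± 2.94 at P60.

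In endothelial cells, Car4, a carbonic anhydrase of capillaries, and Fmo2, a monooxygenase, were higher at P60, and the imprinted fetal RNA H19 and the replication factor Pclaf were lower. Most endothelial cells at P60 lay in a cluster led by Flt1, Plvap, Igfbp3 and Ly6a with 364, 547 and 363 cells there and 0 at P2/3. The cluster that held the P2/3 cells had 534, 118 and 195 of them and 35, 65 and 60 at P60, so the change within the class compares different clusters. Of 12488 genes 1731 were called, 780 higher and 951 lower, with 1112, 934 and 922 called without P2/3 replicate 3 and P60 replicates 1 and 2. Car4 (ENSMUSG00000000805, chr11:84957786-84966044) had 9.33 ± 0.50 (adjusted p = 3.31e-06), from 0.646 CPM through 8.33 to 406 ± 111, and Fmo2 (ENSMUSG00000040170, chr1:162874317-162898726) 6.32 ± 0.44. Enpp6, Ntf3 and Xdh followed at 5.99, 4.81 and 4.74. H19 (ENSMUSG00000000031, chr7:142575529-142578143) had 1937 UMIs at P2/3, 211 ± 81.3 CPM, and 0 at P60, at least 474-fold lower against a floor of 3 counts (adjusted p = 1.44e-05). Pclaf (ENSMUSG00000040204, chr9:65890237-65903266) had -5.13 ± 0.77 (adjusted p = 0.00116). Igf2bp3 and Ppp1r9a followed at -3.88 and -3.56, and Hist1h1b at -4.19 was not called by DESeq2. Without P2/3 replicate 1 Car4 was 8.17, Fmo2 5.52, Enpp6 5.20 and Ntf3 6.25, and without P2/3 replicate 3 Car4 was 10.29 and Enpp6 6.67. Without P60 replicate 2 Pclaf was -4.41 and Hist1h1b -3.49, and without P60 replicate 1 they were -10.05 and -7.88.

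Camera called 13 endothelial lists at the preset correlation. With an estimated correlation the adjusted p was 0.0861 for MHC class I, interferon response, innate sensing, imprinted genes, cholesterol synthesis and collagen, 0.215 for MHC class II, 0.252 for dissociation genes and 0.281 for proliferation, and camera called no list, with 7 at an unadjusted p under 0.05. Of the 13, fry called 9, and not proliferation (0.0592). Endothelial MHC class I had 16 of 20 genes higher and 0 lower (17 and 0 over the list alone, camera adjusted p = 4.03e-16), including H2-K1 (3.59, from 73.4 to 945 CPM) and Psmb9 (3.08). MHC class II had 4 of 5 higher (5 over the list alone, adjusted p = 2.67e-04), with H2-Aa at 0 UMIs at P2/3 and 43 at P60. At P60 the endothelial level of H2-Aa was 0.259% ± 0.104 of the macrophage level, that of Cd74 0.185% ± 0.132, that of H2-Eb1 0.177% ± 0.0627 and that of H2-Ab1 0.347% ± 0.154, against 0.107% ± 0.0582 for the median macrophage marker. The lowest libraries of H2-Ab1 (0.171%) and H2-Aa (0.166%) lay above the highest marker median (0.159%), those of Cd74 and H2-Eb1 did not. The lowest marker lay at 0% in 2 of the 3 P60 libraries, too few counts for a lower bound, and RNA from macrophages stays open for this list. Interferon response had 16 of 35 higher and 1 lower (23 and 1, adjusted p = 8.47e-12), including Gbp2 (2.10), and innate sensing 3 of 16 higher (adjusted p = 0.00172). Proliferation had 25 of 28 lower (27, adjusted p = 4.30e-13) and imprinted genes 13 of 16 lower (14, adjusted p = 2.70e-11), including Igf2 (-2.49, from 592 to 105 CPM). Collagen and matrix had 16 of 28 lower (20, adjusted p = 1.13e-11), including Col18a1 (-2.46). The fibroblast markers Col3a1 (-5.76, and -5.03 to -6.82 with 1 library left out) and Dcn (-4.50) were also lower. Fibroblast RNA in endothelial cells was not measured and stays open for this list. Of all genes called in endothelial cells, 265 of the 951 lower and 76 of the 780 higher lay under 0.25 of another class's level. Cholesterol synthesis had 8 of 20 higher (12, adjusted p = 1.47e-07), including Insig1 (1.57). Dissociation genes had 8 of 25 higher (9, adjusted p = 3.61e-07), including the heat shock gene Hspa1b (3.67). Fenestrated and barrier genes had 5 of 17 higher (5, adjusted p = 0.00891), including Plpp1 (2.13) and Nrp1 (1.96). Angiogenesis genes went both ways, 6 of 22 higher and 2 lower (9 and 8, adjusted p = 0.529), with Kdr at 1.32 and Aplnr at -2.91. Junction genes were lower (0.0304, but 0.386 without P2/3 replicate 1 and 0.0677 without P60 replicate 1). Cytokine genes (0.0461) lost their call without P2/3 replicate 1 (0.245), P2/3 replicate 2 (0.0679), P60 replicate 2 (0.0577) or P60 replicate 3 (0.0548). Glycolysis (0.0412) lost its call without P2/3 replicate 2 (0.189), P2/3 replicate 3 (0.0873), P60 replicate 2 (0.251) or P60 replicate 3 (0.0700).

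In macrophages, MHC class II genes, which present antigen, were among the highest fold changes. H2-Aa (ENSMUSG00000036594, chr17:34282744-34287823) had 7.99 ± 0.53 (adjusted p = 1.67e-09), from 10.8 ± 13 CPM at P2/3 through 168 at P11 to 3013 ± 647 at P60. Cd74 (ENSMUSG00000024610, chr18:60803848-60812652), the chaperone of class II, had 6.27 ± 0.45, from 109 ± 49.4 CPM through 542 to 9188 ± 3192, and H2-Ab1 (ENSMUSG00000073421, chr17:34257689-34269419) 7.49. The chemokine Cxcl9 (ENSMUSG00000029417, chr5:92321347-92328079) had 0 UMIs at P2/3 and 588 at P60, at least 97.3-fold higher (adjusted p = 0.00192), but it lay at 307, 12.5 and 35.7 CPM in the P60 libraries, and without P60 replicate 1 it was at least 14.3-fold higher. Abcg3, Igf2bp3, Tfec, the iron exporter Slc40a1 and Ednrb were lower, at -4.66, -3.94, -3.84, -3.75 and -3.65. Without P2/3 replicate 1 H2-Aa was 7.28, without P2/3 replicate 3 H2-Aa was 8.85 and H2-Ab1 8.17, and without P60 replicate 1 Abcg3 was -6.43 and Tfec -4.43. Of 9631 genes 571 were called, 391 higher and 180 lower, with 347 without P2/3 replicate 1, 315 without P2/3 replicate 3 and 300 by DESeq2. Of the 391 higher genes, 99 lay under 0.25 of the epithelial level and 135 under 0.25 of the level in any other class. Of the 180 lower genes, 14 lay under 0.25 of the level in any other class.

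All 7 macrophage MHC class II genes tested rose, also over the list alone (camera adjusted p = 5.50e-25), and this was the only macrophage list that fry called. With an estimated correlation the adjusted p was 0.0997 for MHC class II and 0.312 for border macrophage genes, and camera called no list, with 3 at an unadjusted p under 0.05. Border macrophage genes had 2 of 15 higher and 4 lower, also over the list alone (adjusted p = 0.00142), with Lyve1 at -3.45 (111 to 11.1 CPM, and -2.86 without P2/3 replicate 3), Pf4 at -1.56 and Cbr2 at 2.96. Microglia-like genes had 5 of 16 higher and 3 lower (6 and 4, adjusted p = 0.146), including Tmem119 (1.71). Dissociation genes had 9 of 25 higher and 0 lower (15 and 2, adjusted p = 1.82e-10), including Hspa1b (5.24, and 5.82 without P2/3 replicate 2). Secreted proteins had 11 of 15 higher (13, adjusted p = 1.73e-14) and ion transport 7 of 19 (9, adjusted p = 3.12e-06), both of epithelial genes such as Enpp2 (4.99, but 5.63 without P2/3 replicate 1 and 4.31 without P60 replicate 3) and Atp1b1 (2.84). Epithelial markers in macrophages lay at 1.76% ± 1.54 of the epithelial level at P2/3 and 7.69% ± 4.08 at P60, and Enpp2 at P60 lay at 1.27 to 1.65 times the lowest epithelial marker share. MHC class I (3.05e-05, 2 of 20 genes), glycolysis (0.00207, 2 of 16), cholesterol synthesis (0.00413, 0 of 18) and complement (0.0131, 2 of 12) were higher. Calls lost when 1 library was left out were those of proliferation, lower (0.00207, and 0.685 without P2/3 replicate 1 and 0.498 without P60 replicate 1), oxidative phosphorylation (0.00473, and 0.290 without P60 replicate 3), interferon response (0.0320, and 0.0909 without P60 replicate 1) and motile cilia (0.00548, but 0.205 without P2/3 replicate 1, 0.0728 without P60 replicate 1 and 0.198 without P60 replicate 3).

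Mural cells were tested only without P60 replicate 1, with 2 P60 libraries. Of 9506 genes 901 were called, 504 higher and 397 lower. Epithelial markers in mural cells lay at 6.71% ± 5.55 of the epithelial level at P2/3 and 23.3% ± 5.23 at P60. By the rule for named genes the 5 highest were Sncg, Cox8b, Timp4, Kcnma1 and Pln. Of these, Cox8b had 0 UMIs at P2/3 and 83 at P60, at a mean of 97.55 CPM. In epithelial cells it lay at 236 and 260 CPM in P60 replicates 2 and 3. An epithelial source of Cox8b in mural cells was not tested. Sncg, Timp4 and Kcnma1 had 1 UMI each at P2/3 and 551, 214 and 62 at P60, and Pln, which regulates the calcium pump of muscle, had 6.03 ± 0.54 (adjusted p = 3.08e-06), from 5.22 to 316 CPM. The 5 lowest were the histone genes Hist1h1b, Hist1h3e and Hist1h1a and the cell cycle genes Ube2c and Birc5, with 0 UMIs at P60. At P2/3 they lay at 225 ± 205, 125 ± 184, 67.7 ± 77.6, 66.7 ± 36.9 and 52.0 ± 9.88 CPM, and the 3 histone genes differed widely between the P2/3 libraries.

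Free RNA was measured as the level of the markers of 1 class in another class, as a share of the level in their own class. Epithelial markers reached 3.68% ± 2.26 in fibroblasts at P2/3, 1.97% at P11 and 6.07% ± 2.94 at P60, and 8.71% ± 7.85, 4.65% and 9.09% ± 4.73 in endothelial cells. In macrophages they reached 1.76% ± 1.54, 1.48% and 7.69% ± 4.08, and in mural cells 6.71% ± 5.55, 6.02% and 23.3% ± 5.23.

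**Figure D4:**
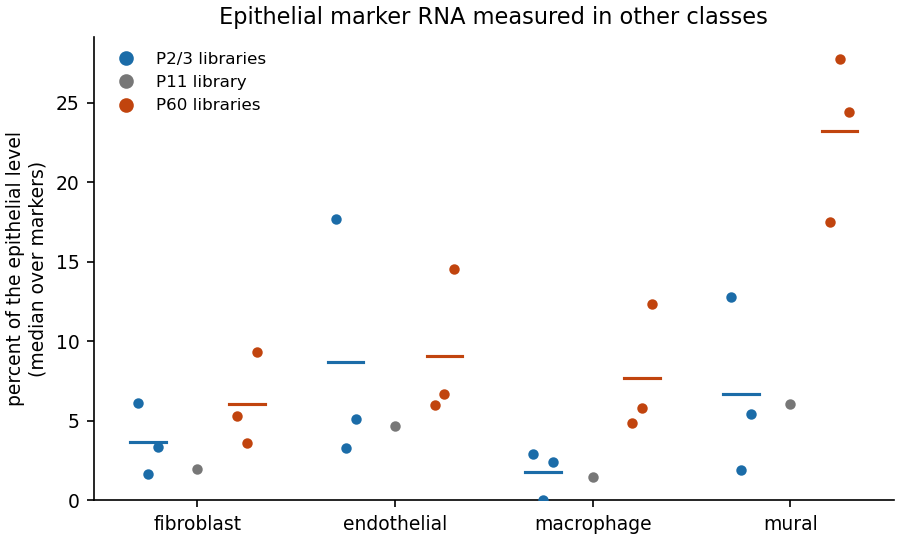
Level of epithelial markers in fibroblasts, endothelial cells, macrophages and mural cells, as a percentage of the epithelial level, for every library. Each point is the median over markers. Epithelial markers in macrophages lay at 1.76% ± 1.54 at P2/3 and 7.69% ± 4.08 at P60.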

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

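The tests of free RNA, of other splits and of differences between cell classes in this part were chosen only after the results were seen. Called genes that changed in opposite directions in epithelial cells and another class between P2/3 and P60 were tested for the difference itself. They had been picked by their opposite calls in the same counts. All 182 in fibroblasts, 139 in endothelial cells and 76 in macrophages passed, so the adjusted p gives no support beyond that choice. The difference is given as the other class minus epithelial cells on the log2 scale, with its adjusted p from edgeR. Against endothelial cells it was 2.95 for Kdr (1.04e-06), 2.45 for Plpp3 (3.29e-06), -3.51 for Igf2 (8.33e-06), 3.76 for Cxcl12 (8.89e-06) and 2.79 for Csf1 (4.40e-05). Against fibroblasts it was 4.53 for Psmb8 (2.91e-07), 2.69 for Plpp3 (5.01e-06), -3.40 for Igf2 (2.18e-05) and 4.18 for Unc5b (4.54e-05), and against macrophages -3.50 for Gbp7 (5.12e-06). Igf2 rose by 1.12 in epithelial cells, with -2.49 in endothelial cells and -2.37 in fibroblasts. Psmb8, an immunoproteasome subunit, had -2.54 in epithelial cells and 2.04 in fibroblasts. With high-scoring doublets kept, the epithelial change of Plpp3 was 0.0137 and those of Cxcl12 and Unc5b were not called. Endothelial RNA in epithelial cells was not measured, so it stays open for the epithelial fall of Kdr, a fixed endothelial marker.

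The first pattern was higher Cd74, H2-Aa, H2-Ab1 and H2-Eb1 in epithelial cells at P60. Free RNA or doublets of macrophages would place these genes near the level of macrophage markers in epithelial cells. Their share of the macrophage level was a median of 2.08 times the lowest marker share, which is consistent with RNA from macrophages. H2-DMb1 lay at least 428 times above that share in each P60 library, which argues against macrophage RNA for this gene. Its change with age in epithelial cells stays open and was not tested against other sources.

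The second pattern was higher Prlr, Enpp2 and Kl at P60 in fibroblasts, endothelial cells and macrophages. Their level, as a share of the epithelial level, was a median of 1.47 times the lowest share of the epithelial markers, so free epithelial RNA may account for it. At P60 the shares were 4.59%, 7.11% and 5.82% for Prlr in the 3 classes. A change within those classes stays open and was not tested.

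The third pattern was lower collagen and matrix genes in epithelial cells at P60, set against fibroblast RNA at P2/3. RNA from fibroblasts would bring all their abundant transcripts alike, and Col1a1 and Col3a1 lay at 0.101% and 0.0688% of the fibroblast level. Of the 20 genes, 17 lay above 3 times the lowest marker share in every P2/3 library. They ran from 3.91 times for Lox and 4.05 for Col6a2 to 212 for Col4a2 and 3158 for Fmod. The markers themselves differed widely, with the highest at 6.71%, 7.84% and 8.41% in P2/3 replicates 1 to 3. With every list member left out of the markers, a choice made after the first outcome was seen, 6 genes lay above. The markers left, Mmp2 and Pdgfra, set a higher bound. These 6 were Col14a1, Fbn1, Sparc, Loxl1, Serpinh1 and Fmod, and their values argue against fibroblast RNA alone for them. Of the rest, Col4a1, Col4a2, Col5a1, Col12a1, Fbn2, Postn, Tnc and Bgn lay at least 19.8 times above the lowest marker share in every P2/3 library. Their levels ran from 2.04% ± 0.611 (Fbn2) to 22.1% ± 27.1 (Tnc) of the fibroblast level, with Bgn at 20.3% ± 2.84. Leaving markers out can only raise the bound, so the values argue against fibroblast RNA alone for them. RNA of other classes was not measured for these genes. Dcn, Lox and Col6a2 stay open, since their outcome changed with the markers. Among them Dcn, itself a marker, lay at 1.17% of the fibroblast level. Lox and Col6a2, at 0.317% and 0.396%, lay under the median marker share of 0.772%. Col1a1, Col3a1 and Fn1, the 3 genes not above that limit, lay at a median of 1.53 times the lowest marker share. They were picked by the same limit, so this value is no test of it, and RNA from fibroblasts stays open for them. A developmental change of all 20 stays open and was not tested apart from other sources.

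For the gene counts between P2/3 and P60, the 6 libraries make 10 splits, which are too few for a share under 0.05, and in each class 1 split, the real one, gave as many genes. The real split gave 7555 genes in epithelial cells, 1969 in fibroblasts and 1731 in endothelial cells, with 0 as the highest other count. In macrophages it gave 571, with 1 as the highest other. Every other split mixed both ages in each set, so the age difference entered the spread within sets. Low counts were bound to follow, and the comparison decides nothing about chance.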

How the results depend on the processing

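The tests without the low-UMI epithelial cluster and under the first naming rule were chosen only after the data were seen. The first naming rule, which left 5972 epithelial cells unnamed, gave 5994 genes between P2/3 and P60, 144 between P2/3 and P11 and 982 between P11 and P60, and turned the epithelial share difference to 1.51 points. The cause of the change to 144 was not tested.

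Between P2/3 and P60 the epithelial count of 7555 lay between 5994 and 7942 under all alternatives that kept every library, and between 4821 and 8201 with 1 library left out. The count of 283 between P2/3 and P11 was 1017 by DESeq2 and 0 with the replicate block, and 33 to 606 with 1 library left out. From P11 to P60 the count of 1288 was 2037 by DESeq2, 260 with the block, and 467 to 2639. Fibroblasts gave 1387 to 2723, and 1061 to 2049 with 1 library left out. Endothelial cells gave 2680 with doublets kept, 1072 with the block, and 922 to 1914. Macrophages gave 300 by DESeq2, 909 with doublets kept, and 315 to 562. The block uses more of the few degrees of freedom, and the cause of the other changes was not tested.

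The epithelial share difference of -0.0959 points became 3.40 with the 40% limit, 3.47 with doublets kept, 0.903 and 1.58 at resolutions of 0.5 and 2, and -2.92 to 2.65 with 1 library left out. The full separation of B cells was lost with the 15% limit (0.364) and the first naming rule (0.390). The other classes kept their sign in every alternative run that named them. B cells had no named cluster with the 40% limit or with doublets kept, and neutrophils had none with the 40% limit. There the cluster led by Igkc and Ly6d scored 0.793 for dendritic cells and 0.751 for B cells. With 1 library left out the differences ran from -3.73 to -0.619 in fibroblasts, 4.15 to 6.65 in endothelial cells and -1.33 to -0.529 in mural cells. They ran from 2.63 to 4.39 in macrophages, 0.495 to 0.979 in T or NK cells and 0.205 to 0.482 in B cells. In erythroid cells they ran from -1.29 to -0.0325 and in neutrophils from -0.166 to -0.0220. The share of epithelial cells with Mki67 or Top2a kept its sign, from -0.125 to -0.0900.

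Camera called 50 lists between P2/3 and P60 over 4 classes, 0 with an estimated correlation, 52 with RLE, 53 with the block and 46 to 52 with 1 library left out. The estimated form also lost interferon response in epithelial cells, where the estimate of 0.01004 was close to the preset 0.01. A call lost in that form therefore need not mean that the genes of the list varied together. The dissociation list between P2/3 and P11 reversed with the block (0.647). With doublets kept, Plpp3 in epithelial cells (0.0137), Kcnj13 (-1.16), Slco1c1 (-0.0476) and Rsph9 (-0.50) in fibroblasts, Rsph9 in endothelial cells (-0.12) and Meg3 in macrophages (0.0651) reversed. Among 462 fold changes of named genes, alternatives other than leaving out a library gave 3026 values with the same call, 151 with a lost call and 58 with a new call, and leaving out 1 library gave 2451, 265 and 39. The estimated correlation is not given from P11 to P60, where it changed with rounding. Mural alternatives other than leaving out P60 replicate 1 were not run.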

Other observations

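The tests in this part were all chosen only after the data were seen. At a resolution of 2 the Deup1 and Ccno cluster had 2 main parts with 1068 of its 1077 cells, and the other 9 are not described. The first held Deup1 at 282 CPM, Cdc20b at 278, Ccno at 148 and the geminin-like regulator Mcidas at 87.8 at P2/3, with Top2a at 155, in 170, 89 and 147 cells at P2/3, 75 at P11 and 0, 0 and 1 at P60. The second held Rmst at 509 CPM, Nkain2 at 383 and the Wnt enhancers Rspo2 and Rspo3 at 152 and 148, in 126, 137 and 190 cells at P2/3, 113 at P11 and 5, 5 and 10 at P60. Its 20 cells at P60 held the ependymal genes Tmem212 at 714 and Ccdc153 at 544 CPM.

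Epithelial cells alone formed 11 clusters. Those led by Klk4, Meg3, Itm2a and Rmrp drew 99.3%, 96.3%, 99.2% and 97.5% of their cells from P2/3 replicate 1, P2/3 replicate 3, the P11 library and P2/3 replicate 2. Those led by Sult1c1, Rdh5 and Spink8 mixed the 3 P60 libraries, with 40.5%, 44.1% and 41.8% from the library that gave most, while one led by Tenm2 drew 66.5% of its 3318 cells from P60 replicate 3 and one of 75 cells led by Slfn5 came from P60 replicate 1 alone. A cluster of 416 cells led by Spink8, Gata3 and Atp10b took 3.78%, 4.03% and 3.77% of the epithelial cells of the P60 libraries and held 0 cells at P2/3 and P11. Since clusters at each age separated by library to a varying degree, cluster sizes were not compared between ages.

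Among epithelial genes called between P2/3 and P60 and with mean levels that differed by at least 1 log2 after 1 CPM was added to each, the 1182 higher genes had gone a median of 45.3% of the way at P11 (quartiles 28.4% and 61.2%), and 94.0% of them lay between both ages. The 1057 lower genes had gone 45.2% (quartiles 25.3% and 64.5%), and 91.2% lay between. Of genes called in epithelial cells and in another class, 182 of 1091 went the opposite way in fibroblasts, 139 of 938 in endothelial cells and 76 of 281 in macrophages.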
